A study of Rattus norvegicus with 12 samples.

How the data were processed

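Total RNA of primary rat microglia was measured on single-colour Illumina rat BeadArrays, with 12 arrays in 4 groups of 3: α-synuclein medium (aSCM) and LacZ control medium (LZCM), each at 6 h and 24 h. Per the labels' protocols, the media came from SH-SY5Y cells infected with adenoviral vectors, kept without serum, cleared of debris by centrifugation and concentrated on filters. The labels' protocols also name a column kit for RNA extraction, a Bioanalyser check of RNA quality and labelling with streptavidin-bound dye by the array maker's manual. Groups and replicate numbers were taken from the sample titles.

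The values tested were the deposited non-normalized table, which holds log2 intensities of 22523 probes per array and was not equalized between arrays, as its array medians differed by up to 0.414. Whether the scanner software had subtracted background is not given in the sources used here. A second deposited table holds the authors' processed log2 values, with a median of 6.92 on every array. R 2.9.1 is named in the submitters' processing notes, and the normalization method is not given in the sources used here. The processed values of an array correlated with its deposited, non-normalized values at r = 0.99932 to 0.99979 across probes. Single processed values lay up to 0.601 from the quantile-normalized deposited values. Together these fix the scale and direction of the processed values. They served as an alternative.

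The design fixed before the data were examined called for limma's neqc, which needs detection p-values. The table holds log2 values without detection p-values, so the fallback written in that design applied: intensities were corrected with normexp (offset 50), log2-transformed and quantile-normalized, and the 50% of probes with the highest mean over the 12 arrays were tested, 11262 in number. The lowest mean kept was 6.68 log2. As a measure of background chosen after the table was seen, a ceiling was set on each array at the 95th percentile of 1275 probes for olfactory and vomeronasal receptors, and lay between 6.68 and 6.80 log2. Of the tested probes, 8887 exceeded it on all 12 arrays, and 71 were receptor probes themselves. Where all 3 arrays of the dimmer group were at or below the ceiling, the difference is given as at least N-fold, as the brighter group's mean over the mean ceiling of the dimmer group's arrays. At the bright end, 55 probes exceeded an intensity of 50000 on at least 1 array, and the highest intensity of an array was 48436 to 62584, so changes of very bright genes can be understated.

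One model with 4 group means was fitted to all 12 arrays with limma's lmFit and eBayes (8 residual and 7.08 prior degrees of freedom), and 5 contrasts were tested two-sided: aSCM against LZCM at each time, their difference (the interaction), and 24 h against 6 h in each medium. P-values were adjusted by Benjamini-Hochberg over the 11262 probes, with a threshold of 0.05. Fold changes are on the log2 scale after an offset was added, which understates the change of dim genes. The 31 gene lists were tested with limma's camera (preset correlation 0.01, two-sided), with 1 probe per gene, the brightest, and Benjamini-Hochberg over the lists; each list had at least 3 tested genes. Each camera call was repeated with an estimated correlation. Overlaps of calls are given beside the number for independent lists, with the odds ratio. On data simulated for the 6 h comparison with 11262 probes, the steps recovered 52.2% of probes changed by 0.5 log2, 90.6% of those changed by 1 and 98.4% of those changed by 2, with fitted medians of 0.38, 0.79 and 1.67 and 7 false calls. Only 67, 64 and 63 probes carried these changes, whereas 61.9% of probes were called in the real 6 h comparison. The simulation therefore does not show how the steps behave when most probes change.

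Gene names came from GEO's platform annotation: 13793 probes had 1 symbol, 0 had several and 8730 are unnamed here. For 13752 named probes the Entrez ID was in the GRCr8 gene table, and 0 symbols changed through it. Of 173 genes with several tested probes, 7 at 6 h and 5 at 24 h had probes called in opposite directions. Genes are named by a rule fixed in advance: for each time, the 15 largest rises and 10 largest falls past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and a fixed set around Toll-like receptor 2; for the interaction and the time contrasts, the 6 largest rises and falls. Nefl and Nefm at 24 h and the changes at each time of genes named for the interaction, were named after their values were seen. Tlr1 belonged to the fixed set and was not analysed here, and another gene of that set is not reported here. Symbols of provisional type were not named.

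The alternatives were no background correction, array medians scaled in place of quantile normalization, the authors' values, no filter on dim probes, only the groups compared in the fit, the replicate number as a block, eBayes with trend and robust, array weights, a minimum fold change of 1.5, each array left out in turn, and for the lists an estimated correlation, the mean of a gene's probes and limma's fry. Added after the table was seen were normexp with an offset of 16, the receptor probes as negative controls, a filter at the ceiling on all 12 arrays, and the homeostatic list without Siglec5. Analyses used R 4.3.3, limma 3.58.1 and the package data.table (1.17.8), and figures Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.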

Results

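Gene expression was measured on 12 Illumina rat BeadArrays of primary rat microglia, the resident macrophages of the brain. The cells had received medium conditioned by differentiated SH-SY5Y cells, a human neuroblastoma line used as a model of neurons. In one medium (aSCM) the SH-SY5Y cells overexpressed human α-synuclein, and in the control medium (LZCM) they overexpressed β-galactosidase from LacZ. Microglia were sampled after 6 h and after 24 h, with 3 arrays in each of the 4 groups, and no untreated microglia were analysed here. The question was how α-synuclein released by neuron-like cells changes microglial gene expression, with Toll-like receptor 2 as the receptor of interest. Each array held 22523 probes, of which 11262 were tested. The median intensity of an array before normalization lay between 109 and 146. Pearson correlations across probes were 0.9952 to 0.9977 between arrays of a group and at most 0.9822 between arrays of different groups. The labels do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.0807.

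At 6 h, Cxcl2, a chemokine for neutrophils, rose in aSCM over LZCM microglia by 6.72 ± 0.14 on the log2 scale (SE, n = 3 arrays per group), Il6 by 6.23 ± 0.12 and Ptgs2, the inducible cyclooxygenase, by 5.92 ± 0.12. The largest falls were in Adap2, a GTPase-activating protein of Arf proteins (-4.51 ± 0.07), and Blnk, an adaptor of immune receptor signalling (-3.42 ± 0.10), while P2ry12, the ADP receptor typical of resting microglia, fell by 3.06 ± 0.11. Of the 11262 probes, 3115 rose and 3861 fell at an adjusted p below 0.05, or 2480 and 4322 with array medians scaled in place of quantile normalization, which takes the share of rises from 44.7% to 36.5%. At least 2-fold changes numbered 665 up and 582 down, and at least 4-fold changes 180 up and 67 down.

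The 15 largest rises also held the CCR6 ligand Ccl20 (5.68 ± 0.11), the hydroxycarboxylic acid receptor Hcar2 (5.57 ± 0.11), the adenosine receptor Adora2a (5.44 ± 0.14), the early activation marker Cd69 (5.18 ± 0.15) and the chemokine Ccl4 (5.08 ± 0.15). Nos2, the inducible nitric oxide synthase, was not above the background ceiling on any LZCM array at 6 h and was at least 26.2-fold higher in aSCM. Il1a (4.90), Plet1 (4.85), the C-type lectin Clec4e (4.82), the granulocyte growth factor Csf3 (4.80), the caspase-8 inhibitor Cflar (4.75) and the oxysterol-forming enzyme Ch25h (4.63) completed the set. The other large falls were in Asb2 (-3.42), Tmem37 (-3.40), the G-protein subunit Gna15 (-3.40), the fucosyltransferase Fut7 (-3.34), the deglycosylating enzyme Engase (-3.33), Klhl6 (-3.32) and the cytokine receptor Il21r (-3.25). Adjusted p ran from 1.5e-15 to 4.5e-13 over these rises and from 2.9e-16 to 6.4e-12 over these falls. By the rule that named the largest rises and falls, all 3 arrays of one medium lay beyond all 3 of the other in each.

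Among the genes fixed in advance, Tnf rose by 4.12 ± 0.10 at 6 h, Cxcl1 by 4.62 ± 0.14, Ccl5 by 3.01 ± 0.08, Ccl2 by 2.65 ± 0.09 and Il1b by 2.43 ± 0.18. Il1b averaged 15.52 log2 in aSCM, close to the top of the scanner's range, where a rise can be understated. Tlr2 rose by 1.03 ± 0.07 (adjusted p = 4.1e-09) and Cd14, a co-receptor of Toll-like receptors, by 1.08 ± 0.08 (8.9e-09). Tlr4, the receptor of lipopolysaccharide, fell by 1.30 ± 0.07 (1.2e-10). Tlr6, a partner of Tlr2, differed by -0.08 ± 0.08 (adjusted p = 0.39). The adaptor Myd88 fell by 0.21 ± 0.07 (adjusted p = 0.019), a call lost without LZCM replicate 2 (0.0687), without aSCM replicate 1 (0.086), without aSCM replicate 2 (0.0588) and with no filter on dim probes (0.0539), with a range over the alternatives of 0.00258 to 0.086.

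**Figure D1:**
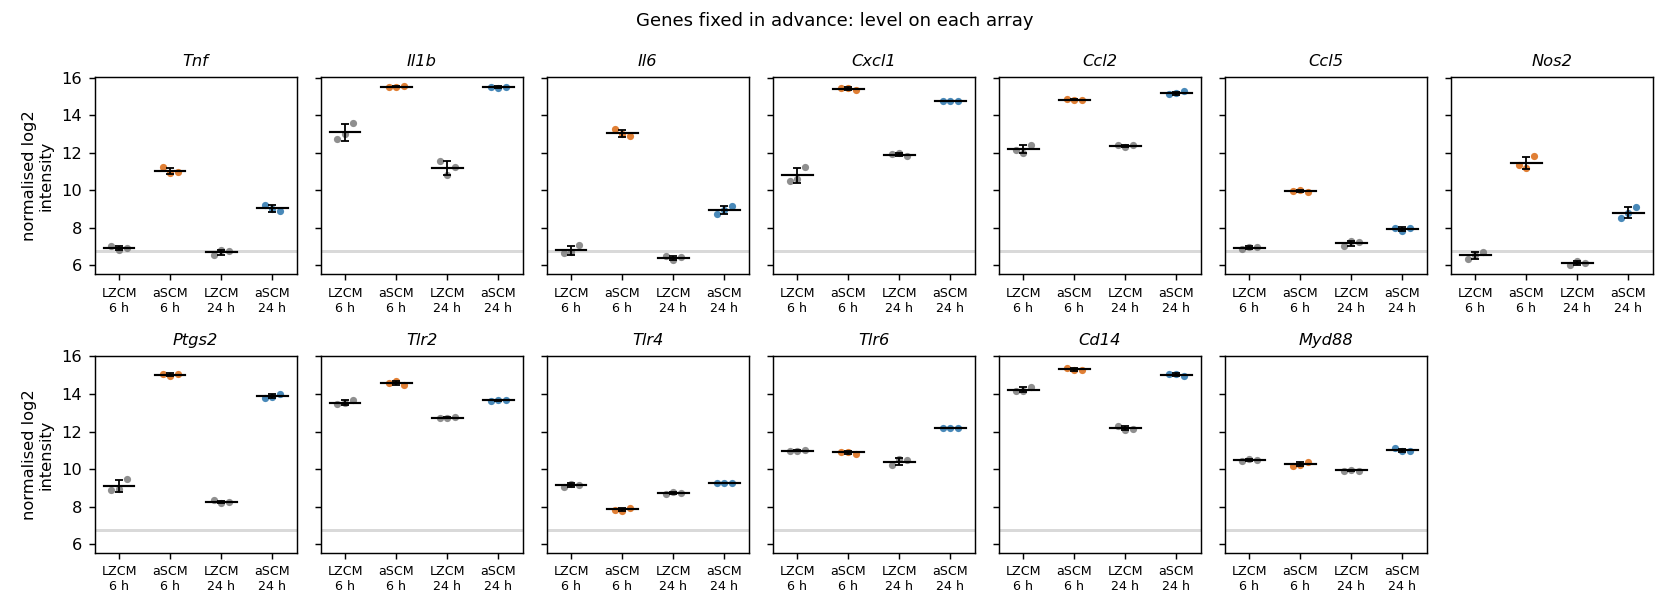
Normalised log2 intensity on each array for the 13 tested genes fixed in advance, with points for arrays, lines for group means and bars for the SD of 3 arrays; the grey band is the background ceiling (6.68 to 6.80). At 6 h Tlr2 was higher by 1.03 and Tlr4 lower by -1.30 in aSCM, and at 24 h Tlr6 was higher by 1.79.

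Of the 31 gene lists, 11 were higher and 6 lower in aSCM at 6 h by camera, which compares a list with all other genes. In the inflammatory cytokines, 13 of 14 tested members rose, among them Il6, Csf3, Il10 (3.60) and Tnf, and none fell. Their median change was 2.93, or 2.77 with members below the ceiling set to their bound (camera adjusted p = 1.67e-09). Chemokines rose in 13 of 18 members and fell in 1, with a median of 2.63 (1.6e-06; adjusted p = 0.115 with an estimated correlation). In the NF-kB components and feedback regulators, 14 of 15 rose and 1 fell, with Cflar, the mRNA-degrading regulator Zc3h12a (3.00), Tnfaip2 (3.11) and Nfkb1 (2.74) as examples (1.59e-08). Immediate-early genes rose in 15 of 20 members and fell in 2, led by the transcription factors Nr4a3 (2.85) and Atf3 (2.83) and by Ier3 (2.42), with an adjusted p of 5.03e-07. Interferon-stimulated genes rose in 23 of 33 and fell in 3, among them Oasl (2.85), the ISG15 protease Usp18 (2.41) and the GTPases Gbp5 (2.28) and Gbp2 (2.03); the list's adjusted p was 1.6e-06, and adjusted p = 0.173 with an estimated correlation.

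In the unfolded protein and amino acid response list, 16 of 23 genes rose and 4 fell at 6 h, with Atf3, Cebpb (2.02) and Atf4 (1.90) as examples (camera adjusted p = 2.33e-05). Slc7a11, the cystine transporter that this list shares with the NRF2 targets, was at least 7.64-fold higher in aSCM. NRF2 targets rose in 10 of 15 members and fell in 1, with the thioredoxin reductase Txnrd1 at 2.37 and Me1 at 0.84 (0.00179; adjusted p = 0.115 with an estimated correlation). Inflammasome and cell-death genes rose in 14 of 17 members, such as Nlrp3 (2.97), Ripk2 (2.50) and Bcl2a1 (2.00), and fell in 3, with the adaptor Pycard at -2.39 (0.00179). Prostaglandin, nitric oxide and NADPH oxidase enzymes rose in 10 of 17, with the citrulline-using enzyme Ass1 at 3.73 and the prostaglandin E synthase Ptges at least 8.18-fold higher, and fell in 5. Their median was 2.21, or 2.11 with bounds (0.00655; adjusted p = 0.115 with an estimated correlation). Matrix proteases and inhibitors rose in 11 of 15, with Serpinb2 at 2.98 and Mmp14 at 2.85, and fell in 2, with the plasminogen activator Plau at -2.27 (0.00179; adjusted p = 0.116 with an estimated correlation). Alternative-activation markers rose in 10 of 13 and fell in 1, among them Il10, Arg1 (2.81), Klf4 (2.33) and the feedback inhibitor Socs3 (at least 7.69-fold), with an adjusted p of 2.24e-04. Il10 is shared with the cytokine list, Arg1 with the nitric oxide list and Klf4 with the immediate-early list. This call is therefore not independent of theirs.

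Cell-cycle genes were lower in aSCM at 6 h: 25 of 29 fell and none rose, with a median of -0.97 (camera adjusted p = 2.95e-07). Examples were the mitotic kinases Ttk (-1.92), Aurkb (-1.51) and Cdk1 (-1.32) and the cyclin Ccnb2 (-1.81). Over the same arrays, oligodendrocyte-lineage markers fell in 8 of 11 with none rising (0.0306; adjusted p = 0.276 with an estimated correlation), with Sox10 at -1.62, Olig1 at -1.19 and Ugt8 at -0.97; this call was lost with receptor probes as negative controls, a setting chosen after seeing the data (0.0526, range over the alternatives 1.8e-05 to 0.276). Astrocyte markers fell in 7 of 10 and rose in 1 without passing the list test (0.0792), with the glutamate transporter Slc1a3 at -1.78 and Sparcl1 at -1.17. Microglial homeostatic genes fell in 13 of 21 and rose in 3, with the purinergic receptor P2ry13 at -2.35, Rgs10 at -1.52 and the fractalkine receptor Cx3cr1 at least 4.07-fold lower. Their median was -0.43, or -0.32 with bounds (0.00659; adjusted p = 0.115 with an estimated correlation). Microglia and macrophage markers fell in 8 of 11 and rose in 2 (0.0792), among them the actin-binding Coro1a (-0.77), Laptm5 (-0.62) and Tyrobp (-0.46), and passed with no filter on dim probes (0.0148, range 7.01e-08 to 0.314).

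Lysosome and autophagy genes fell in 16 of 27 and rose in 2 at 6 h (camera adjusted p = 0.0072; adjusted p = 0.115 with an estimated correlation). Examples were the protease Ctsc (-2.02), Gusb (-1.30) and Ppt1 (-1.17), while the autophagy receptor Sqstm1 gave 1.47, 1.19 and -0.26 on its 3 probes. Oxidative phosphorylation genes fell in 18 of 26 and rose in 1, with Ndufa8 at -1.01 and Sdhd at -0.67 (0.00616; adjusted p = 0.116 with an estimated correlation). LXR targets fell in 9 of 12, such as the sterol exporter Abcg1 (-1.43), Smpdl3a (-0.95) and Scd2 (-0.90), and only Abca1 rose (0.85), with an adjusted p of 0.043 and adjusted p = 0.116 with an estimated correlation. With array medians scaled in place of quantile normalization, the calls were lost for oxidative phosphorylation (0.187), lysosome (0.0578) and LXR targets (0.0825), for which the alternatives ranged from 1.73e-07 to 0.187, 5.61e-08 to 0.115 and 5.34e-08 to 0.116; LXR targets also lost theirs without aSCM replicate 2 (0.0533) or 3 (0.0512) of 6 h. Over only the probes above the background ceiling on all 12 arrays, a filter chosen after seeing the data, matrix proteases (0.0735, range 1.33e-07 to 0.116), homeostatic genes (0.0564, 4.34e-09 to 0.115), prostaglandin and nitric oxide enzymes (0.123, 6.85e-10 to 0.123) and LXR targets (0.0648) did not pass.

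The other lists did not pass at 6 h. Toll-like receptors and adaptors rose in 7 of 15 and fell in 6, with the kinases Irak2 (2.38) and Irak3 (1.25) and the RNA receptor Tlr7 (1.44) higher; the median was -0.02, while the mean, 0.26, and the test (adjusted p = 0.374) pointed up. In antigen presentation, 8 of 21 rose, such as Cd40 (3.89), Icam1 (2.81) and Cd86 (1.73), and 3 fell, such as RT1-DMb (-1.61), with an adjusted p of 0.126 and of 0.0414 with scaled medians (range 2.02e-06 to 0.296). Lipid-associated microglia genes fell in 11 of 19, such as Clec7a (-0.98), Lgmn (-0.78) and Axl (-0.76), and rose in 4 (0.276). Complement and Fc receptor genes rose in 3 of 16, with Fcgr2b at 1.97 and Cfb at 0.81, and fell in 6, with the anaphylatoxin receptor C3ar1 at -1.99 (0.579). Glycolysis genes rose in 9 of 21, with the lactate transporter Slc16a1 at 1.59, and fell in 5, with Pfkp at -1.37 and Pdk1 at -0.76 (0.276). Cholesterol genes rose in 3 of 17 and fell in 8, with Idi1 at 0.58 and Ebp at -0.78 (0.479). Ribosomal proteins rose in 4 of 31 and fell in 3, with Rplp2 at 0.83 and Rps2 at -0.27, the latter call lost with scaled medians (adjusted p = 0.126, range 3.72e-04 to 0.126); the list test pointed up against a median of -0.05 and a mean of -0.01 (0.997). Of 9 heat shock genes, Hsp90aa1 rose (0.54) and Hspe1 fell (-0.17); the list's adjusted p was 0.457. The Hspe1 call was lost without LZCM replicate 1 (0.055) or 2 (0.101), without aSCM replicate 1 (0.0575), 2 (0.0605) or 3 (0.05), with no filter on dim probes (0.092) and in the authors' values (0.0517), with a range of 0.015 to 0.101.

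Among the remaining cell type markers at 6 h, neuronal markers rose in 3 of 9, with the neurofilaments Nefl (1.01) and Nefm (0.80) among them, and fell in 2, with Stmn2 at -1.03 (camera adjusted p = 0.479). Fibroblast and pericyte markers rose in 2 of 6, with Mgp at 1.29, and fell in 4, with Col1a2 at -0.52 (0.866). Of 4 endothelial markers, Esam rose (0.61) and none fell (0.465). Lymphocyte and granulocyte markers rose in 2 of 5, with S100a8 at 0.43, and fell in 2, with Cd8b at -0.67; the test pointed up against a median of -0.11 and a mean of -0.08 (0.997). Counts adjusted over the list alone equalled those over all probes at 6 h except for cholesterol (4 up, 8 down), glycolysis (10 up, 5 down), heat shock (1 up, 0 down) and ribosomal proteins (3 up, 1 down).

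**Figure D2:**
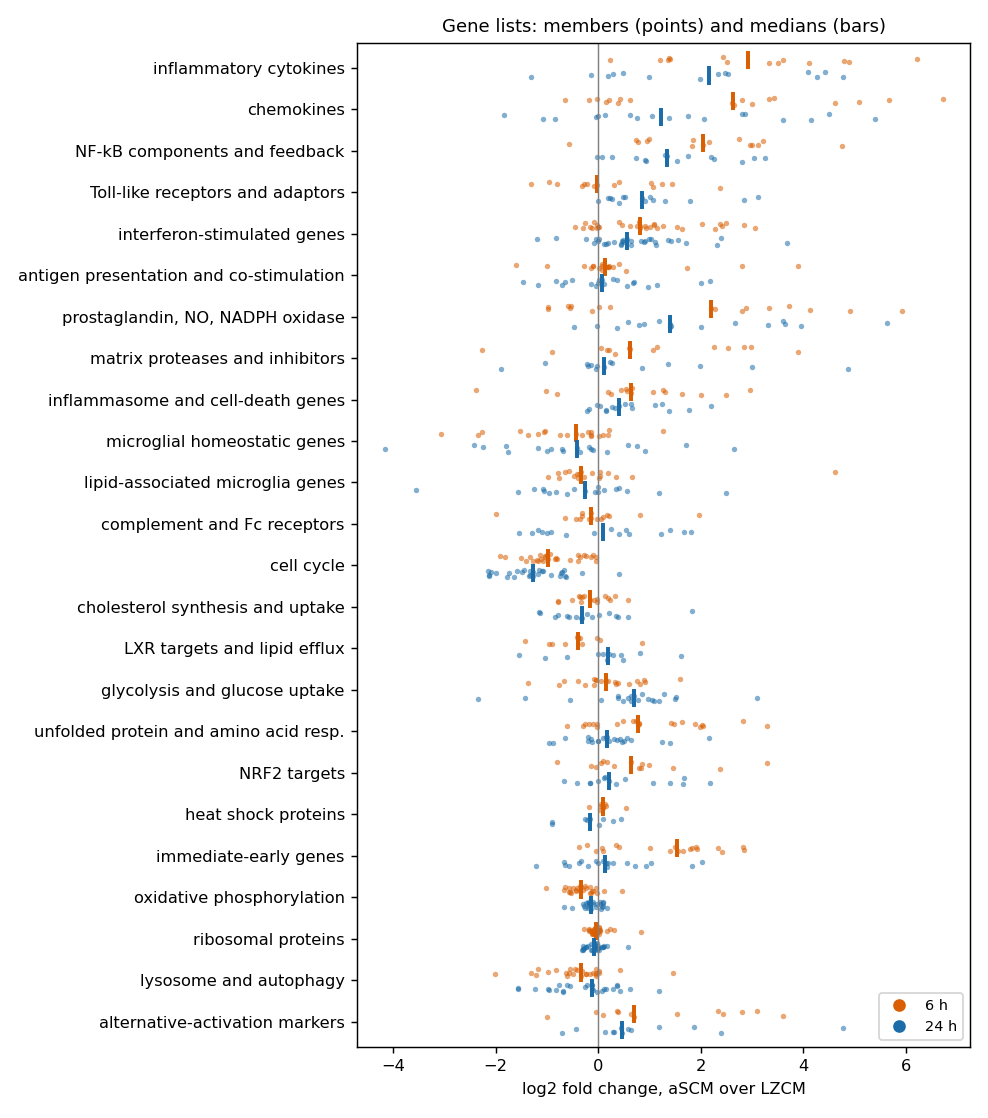
Fitted log2 change of aSCM over LZCM at 6 h (orange) and 24 h (blue) for the tested members of the functional gene lists; points are genes at their fitted values, also where a group was below the ceiling, and bars are list medians. Inflammatory cytokines had medians of 2.93 and 2.17, and cell-cycle genes of -0.97 and -1.26.

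At 24 h, Upp1, the uridine phosphorylase, rose in aSCM over LZCM microglia by 6.27 ± 0.09 (SE, n = 3 arrays per group), Slpi, an inhibitor of leukocyte proteases, by 6.19 ± 0.13 and Ptgs2 by 5.64 ± 0.12. The largest falls were in Ccn2, the connective tissue growth factor (-4.98 ± 0.09), the organic anion transporter Slco2b1 (-4.15 ± 0.10) and, further down, the lipoprotein lipase Lpl (-3.56 ± 0.10). Sparcl1, which astrocytes secrete, and Bcas1, a gene of the oligodendrocyte lineage, also fell (-3.27 ± 0.07 and -3.31 ± 0.08). Across the array, 3746 of 11262 probes rose and 3410 fell, or 2878 and 3524 with array medians scaled, so that rises made up 52.3% or 45.0% of the calls. By the quantile-normalized values, 535 probes rose and 762 fell by at least 2-fold, and 139 rose and 143 fell by at least 4-fold.

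Other large rises at 24 h were in Cxcl2 (5.41 ± 0.14), the aldo-keto reductase Akr1b8 (5.37 ± 0.08), the chemokine Ccl12 (5.01 ± 0.20), the gelatinase Mmp9 (4.87 ± 0.14), Il10 (4.77 ± 0.08) and Ccl4 (4.51 ± 0.15). Wfdc21 (4.47), Il1a (4.43), Adora2a (4.43), the siderophore-binding Lcn2 (4.29), Il1b (4.27) and Ccl7 (4.16) followed. Pnlip, a lipase (-3.69), Plxdc2 (-3.64), Ctla2a (-3.53), the EGF receptor ligand Tgfa (-3.50) and the tetraspanin Tspan2 (-3.42) were the other large falls. Adjusted p ran from 1.7e-16 to 1.2e-11 over the rises and from 2.5e-15 to 1.4e-13 over the falls. Among the genes fixed in advance, Cd14 rose by 2.84 ± 0.08, Tlr6 by 1.79 ± 0.08, Myd88 by 1.08 ± 0.07, Tlr2 by 0.92 ± 0.07 and Tlr4 by 0.53 ± 0.07. Cxcl1 rose by 2.86 ± 0.14, Ccl2 by 2.80 ± 0.09, Tnf by 2.34 ± 0.10 and Ccl5 by 0.76 ± 0.08. Il6 and Nos2 were not above the ceiling on any LZCM array at 24 h and were at least 4.73-fold and at least 4.33-fold higher in aSCM.

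Of the 31 lists, 9 were higher and 6 lower in aSCM at 24 h. Prostaglandin, nitric oxide and NADPH oxidase enzymes rose in 15 of 17 and fell in 1, with the superoxide dismutase Sod2 at 3.96, the tetrahydrobiopterin enzyme Gch1 at 3.64 and the oxidase subunit Ncf4 at 3.60 (camera adjusted p = 7.86e-07). In the NF-kB list, 13 of 15 rose and none fell, with Birc3 (3.25), Nfkbiz (3.05) and Map3k8 (2.27) as examples (1.68e-06). Toll-like receptors and adaptors rose in 13 of 15 with none falling, among them Irak3 (3.11), Cd14, Tlr6 and Tlr7 (1.31), with an adjusted p of 2.49e-05. From 6 h to 24 h this list fell in LZCM, in 13 of 15 members with a median of -0.66. In aSCM it did not shift as a whole over that time (median 0.07, 6 rose and 6 fell, camera adjusted p = 0.952). The difference at 24 h is therefore no general late rise in aSCM. Single members did rise there: Tlr6 lay at 10.797 to 10.934 log2 on the aSCM arrays at 6 h and at 12.176 to 12.214 at 24 h. Tlr4 lay at 7.787 to 7.945 and at 9.248 to 9.276. Microglia and macrophage markers also fell in LZCM over that time, with a median of -0.37. Dilution of microglial RNA by other cells was not tested for this list. Interferon-stimulated genes rose in 24 of 33 and fell in 3, with Usp18 at 3.68, Oasl at 2.40 and the transcription factor Irf7 at 2.31 (6.51e-05; adjusted p = 0.28 with an estimated correlation). Inflammatory cytokines rose in 11 of 14 and fell in 1, with the IL-1 receptor antagonist Il1rn at 4.10; their median was 2.17, or 2.12 with bounds (8e-05; adjusted p = 0.0612 with an estimated correlation). Chemokines rose in 12 of 18 and fell in 3, with Ccl3 at 3.61 (0.00157; adjusted p = 0.25 with an estimated correlation).

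Glycolysis and glucose uptake genes rose in 17 of 21 and fell in 3 at 24 h, with the lactate exporter Slc16a3 at 3.10 and Pgk1 at 1.19, while Aldoc, also an astrocyte marker, fell by 2.35 (camera adjusted p = 3.76e-04; adjusted p = 0.0612 with an estimated correlation). Inflammasome and cell-death genes rose in 10 of 17 and fell in 1, with Bcl2a1 at 1.78, Bid at 1.38 and Nlrp3 at 1.25 (0.00427). Alternative-activation markers rose in 10 of 13 and fell in 2, with Il10, shared with the cytokine list, Socs3 (2.39) and Il4r (1.88) as examples. Their median was 0.46, or 0.45 with bounds (camera adjusted p = 0.00501, or adjusted p = 0.0506 with an estimated correlation). Microglial homeostatic genes fell in 13 of 21 and rose in 5, with Slco2b1 and the lipid receptor Trem2 (-2.24) lower and the integrin Itgam (1.72) and Siglec5 (2.65) higher (0.0261; adjusted p = 0.17 with an estimated correlation). Siglec5 stood in this list as an older symbol of Siglech, which is doubtful; without it, 13 of 20 fell and 4 rose (0.0066, range over the alternatives 2.26e-08 to 0.17).

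Cell-cycle genes fell in 28 of 29 and rose in 1 at 24 h, with a median of -1.26 (camera adjusted p = 2e-12); Cdk1 and Ccna2 both fell by 2.12, Kif11 by 2.00 on its brightest probe (-0.31 on the other, adjusted p = 0.0012) and Ube2c by 1.59. Markers of other brain cells fell in the same comparison. Astrocyte markers fell in 9 of 10 with none rising and a median of -1.94 (2.51e-06), with Mt3 at -3.22 and Slc1a3 at -2.75. All 11 oligodendrocyte-lineage markers fell, with a median of -1.83 (2.51e-06; adjusted p = 0.0506 with an estimated correlation), among them Ugt8 (-2.81), Olig1 (-2.74) and Sox10 (-1.76), with the junction protein Cldn11 at least 4.74-fold lower. Fibroblast and pericyte markers fell in 5 of 6 with none rising (0.00467; adjusted p = 0.0612 with an estimated correlation), with the collagen Col1a2 at -2.98 and Fn1 at -1.91. Neuronal markers fell in 7 of 9, with Stmn2 at -3.09, Gad1 at -2.18 and Tubb3 at -1.23, and the remaining Nefl (0.77) and Nefm (0.49) rose (0.00963; adjusted p = 0.0729 with an estimated correlation). Microglia and macrophage markers rose in 4 of 11, such as Spi1 (1.58) and Coro1a (0.86), and fell in 3, such as Ctss (-0.82); the median was -0.08, while the mean, 0.27, and the test (0.667) pointed up.

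**Figure D3:**
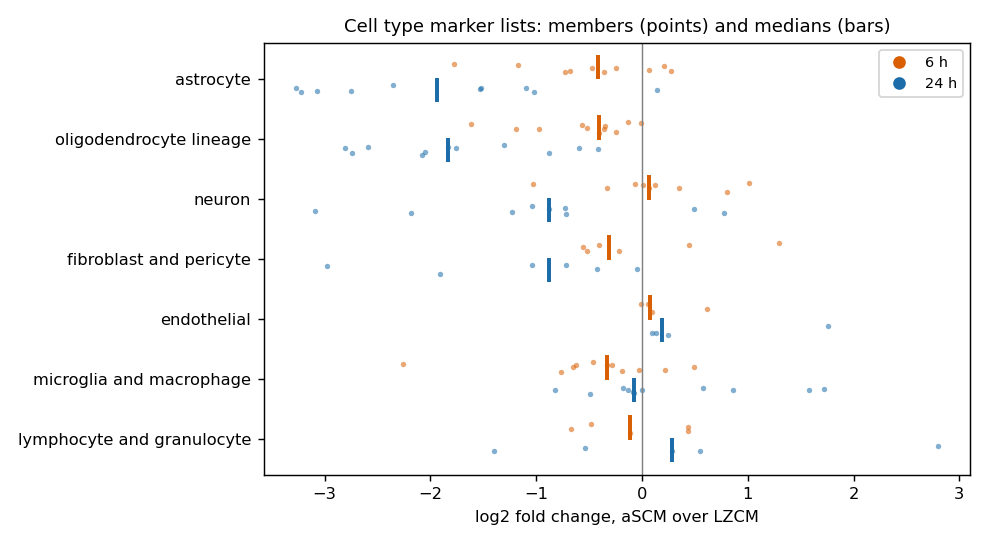
Fitted log2 change of aSCM over LZCM at 6 h (orange) and 24 h (blue) for the tested members of the cell type marker lists; points are genes at their fitted values, also where a group was below the ceiling, and bars are list medians. At 24 h the astrocyte and oligodendrocyte-lineage medians were -1.94 and -1.83, against -0.08 for microglia and macrophage markers.

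The remaining lists did not pass at 24 h. NRF2 targets rose in 8 of 15, with the quinone reductase Nqo1 at 2.19, Gsr at 1.67 and Me1 at 1.66, and fell in 2 (camera adjusted p = 0.0513). Lysosome and autophagy genes rose in 6 of 27, with the sialidase Neu1 at 1.18, and fell in 13, with Hexa at -1.56 and Ppt1 at -1.24 (0.0513). Lipid-associated genes rose in 5 of 19, with Ch25h at 2.50, and fell in 10, with Lpl, Axl (-1.07) and Npc2 (-1.05) among them (0.111). Oxidative phosphorylation genes fell in 11 of 26 and rose in 1, with Ndufa1 at -0.66 and Cox8a at -0.51 (0.142). In cholesterol synthesis, Stard4 (1.84) was among 4 of 17 that rose, and Dhcr7 (-1.15) and Idi1 (-1.14) among 10 that fell (0.158). The unfolded protein list rose in 12 of 23, with Cebpb at 2.16 and Ero1a at 1.24, and fell in 5, with Herpud1 at -0.87 (0.185). Matrix proteases rose in 7 of 15, with Mmp3 at least 7.27-fold higher and Mmp14 at 1.98, and fell in 4, with Plau at -1.90 (0.321). LXR targets rose in 6 of 12, with the receptor Nr1h3 at 1.62, and fell in 3, with Apoc1 at -1.55 (0.463). Antigen presentation genes rose in 9 of 21, with RT1-N3 at 2.18 and Cd40 at 2.01, and fell in 6, with Cd83 at -1.46 (0.532). Immediate-early genes rose in 8 of 20, with Ier3 at 2.02 and Dusp1 at 1.84, and fell in 6, with Egr1 at -1.21 (0.606).

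Complement and Fc receptor genes rose in 8 of 16 at 24 h, with C3ar1 at 1.81 and C1r at 1.68, and fell in 7, with Serping1 at -1.54 and C1qa at -1.18; the test pointed down (camera adjusted p = 0.707) against a median of 0.09 and a mean of 0.01. Heat shock proteins rose in 2 of 9, with Dnaja1 at 0.45, and fell in 4, with Hspb1 at -0.90 (0.468). Ribosomal proteins rose in 1 of 31, Rpl5 at 0.59, and fell in 7, with Rps15 at -0.32 (0.312). Endothelial markers rose in 2 of 4, Esam at 1.76 and Cldn5 at 0.25 (0.212). The Cldn5 call (adjusted p = 0.019) was lost without LZCM replicate 3 (0.0938), aSCM replicate 2 (0.0907) or aSCM replicate 3 (0.0766) of 24 h and with scaled medians (0.199), with a range over the alternatives of 0.000737 to 0.199. Lymphocyte and granulocyte markers rose in 2 of 5, with S100a8 at least 5.95-fold higher, and fell in 2, with Cd8b at least 2.08-fold lower (0.671). Adjusted over the list alone, the counts at 24 h differed for oxidative phosphorylation (0 up, 6 down), ribosomal proteins (1 up, 6 down), LXR targets (7 up, 3 down), heat shock (2 up, 5 down), immediate-early genes (9 up, 7 down) and lymphocyte markers (3 up, 2 down). NRF2 targets passed with scaled medians (0.00605), no filter on dim probes (0.0232), eBayes with trend and robust (0.036), array weights (0.0499) and the mean of a gene's probes (0.0409), and without LZCM replicate 1 (0.0384), aSCM replicate 1 (0.0451) or aSCM replicate 3 (0.0409) of 24 h, with a range over the alternatives of 1.96e-07 to 0.28. The lysosome list passed with no filter on dim probes (0.015), with eBayes with trend and robust (0.0412), with the filter at the ceiling (0.0397), and without LZCM replicate 2 of 6 h (0.0474), LZCM replicate 1 of 24 h (0.0444) or aSCM replicate 1 of 24 h (0.045), with a range of 3.62e-07 to 0.24. Lipid-associated genes passed with no filter on dim probes (0.0403) and with the filter at the ceiling (0.0396), with a range of 2.55e-07 to 0.327, and the Rps15 call was lost with scaled medians (adjusted p = 0.0851, range 2.67e-05 to 0.0851).

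Of the probes that rose at 6 h, 1659 also rose at 24 h against 1036 for independent lists (odds ratio 3.31), and 1883 fell at both times against 1169 (odds ratio 3.66). The group means came from different arrays at the 2 times, but the normalization, the filter and each probe's estimated spread were shared, so the lists were not independent and the overlap was not tested against chance. With the 6 arrays of each time fitted alone, still normalized and filtered together, 1591 rose and 1852 fell at both times, against 1008 and 1148 for independent lists. At least 2-fold in the same direction at both times were 201 rising and 158 falling probes. The effect of the medium itself differed between the times for many genes: in the interaction, 3426 probes had a higher log2 effect at 24 h than at 6 h and 3133 a lower one. Ccl20 rose by 5.68 at 6 h and fell by 1.09 at 24 h, Gdf15, a stress-induced cytokine, rose by 4.23 and fell by 0.36, and Plpp3, a lipid phosphatase, rose by 4.11 and fell by 0.43. The reverse order was seen for C3ar1 (-1.99 at 6 h, 1.81 at 24 h), Il21r (-3.25, 0.86) and Tmem37 (-3.40, 1.02). Of 214 genes named for either time, 188 passed the interaction test, against 58.2% of all tested probes. Besides the fixed set, these genes were named by their changes in these data, which favours a call. Tlr2 did not pass (adjusted p = 0.38), while Tlr4 (3.2e-10), Tlr6 (1.3e-09) and Cd14 (3.1e-09) did. Cd14 lay at 15.26 to 15.413 log2 on the aSCM arrays at 6 h and at 14.946 to 15.088 at 24 h. On the LZCM arrays it lay at 14.175 to 14.367 and at 12.1 to 12.324. Its interaction thus came with a fall in LZCM and no rise in aSCM.

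In LZCM microglia, the astrocyte filament Gfap rose from 6 h to 24 h by 2.24 ± 0.09 (SE, n = 3 arrays per group), Cspg5 by 2.19 ± 0.08, the acyl-CoA thioesterase Acot1 by 2.16 ± 0.07, the oligodendrocyte factor Olig1 by 2.13 ± 0.08, Dbx2 by 2.09 ± 0.10 and Sparcl1 by 2.00 ± 0.07. The falls were led by Cxcl10, an interferon-induced chemokine (-3.27 ± 0.16), Cxcl13 (-3.26 ± 0.17), the itaconate-forming enzyme Acod1 (-2.76 ± 0.15), Ccl12 (-2.75 ± 0.20) and Cxcl11 (-2.45 ± 0.14), and Cd69 was at least 4.88-fold lower. Interferon-stimulated genes fell in 28 of 33 members (camera adjusted p = 1.55e-12; adjusted p = 0.0857 with an estimated correlation), Toll-like receptors and adaptors in 13 of 15 (1.24e-07) and antigen presentation genes in 16 of 21 (4.16e-07). Astrocyte markers rose in 9 of 10 (9.25e-07), and microglia and macrophage markers fell in 10 of 11 (6.5e-04). Adjusted over the list alone, 29 interferon-stimulated and 17 antigen presentation genes fell, and the other counts given were equal. In all, 2331 probes rose and 2400 fell, or 1654 and 2686 with array medians scaled, which takes the share of rises among the calls from 49.3% to 38.1%. Of the 31 lists, 5 were higher and 11 lower at 24 h, and 1 and 5 with an estimated correlation.

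In aSCM microglia, Upp1 rose by 4.72 ± 0.09 from 6 h to 24 h (SE, n = 3 arrays per group), Tmem37 by 4.35 ± 0.07, Rhoj by 3.58 ± 0.08, Slpi by 3.58 ± 0.13, Adap2 by 3.58 ± 0.07 and Prxl2b by 3.48 ± 0.07. The falls were led by Tbc1d17 (-5.08 ± 0.09), Ccl20 (-5.01 ± 0.11), the chemerin receptor Ccrl2 (-4.88 ± 0.07), the scavenger receptor Olr1 (-4.54 ± 0.08), Clec4e (-4.52 ± 0.10) and Cxcl10 (-4.50 ± 0.16). Interferon-stimulated genes fell in 27 of 33 (camera adjusted p = 9.51e-07; adjusted p = 0.207 with an estimated correlation), immediate-early genes in 15 of 20 (5.6e-05) and NF-kB genes in 12 of 15 (7.49e-05; adjusted p = 0.0539 with an estimated correlation). Astrocyte markers fell in 6 of 10 and rose in 1 (0.0405; adjusted p = 0.148 with an estimated correlation), and counts adjusted over the list alone were equal for these lists. Over time, 4027 probes rose and 3461 fell; 2 lists were higher and 12 lower, and 0 and 1 with an estimated correlation.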

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

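The tests of scaling, of marker loss, of cell-cycle genes against markers and of interferon genes against markers were chosen after the results were seen; the interaction and the splits of the arrays were planned.

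The interaction term drew attention to genes whose response to the medium differed between 6 h and 24 h: 3426 probes with a higher and 3133 with a lower effect at 24 h, and 188 of the 214 genes named for either time. The called probes were 58.2% of those tested. Besides the fixed set, the 214 genes were named by their changes in these data, which favours a call. The effect was higher at 24 h by 4.42 log2 for Tmem37, 4.36 for Upp1, 4.26 for Adap2, 4.11 for Il21r, 3.84 for Slpi and 3.80 for C3ar1. It changed by -6.76 for Ccl20, -4.59 for Gdf15, -4.53 for Plpp3, -4.22 for Noct, -3.97 for Sfrp2 and -3.97 for Ccn2. Among the lists, the effect was lower at 24 h for immediate-early genes (camera adjusted p = 1.73e-04; adjusted p = 0.0313 with an estimated correlation), astrocyte markers (1.73e-04; 0.0313), oligodendrocyte-lineage markers (0.001; 0.142), neuronal markers (0.00121; 0.0689), cell-cycle genes (0.00384; 0.109), the unfolded protein list (0.00968; 0.0689), fibroblast and pericyte markers (0.0165; 0.137) and inflammatory cytokines (0.0315; 0.31), in which 9 of 14 members passed downwards, or 10 adjusted over the list alone. It was higher for Toll-like receptors (0.0202; 0.142), glycolysis (0.0332; 0.275) and microglia and macrophage markers (0.0332; 0.142), each second value being the adjusted p with an estimated correlation.

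Splitting the 6 arrays of a comparison into 3 and 3 allows 10 splits, too few for a share under 0.05. By limma on those 6 arrays, the real split gave 6863 calls at 6 h, 7108 at 24 h, 4994 over time in LZCM and 7176 over time in aSCM, each the 1 split with as many, and the highest other split 0 (up to 134, 138, 233 and 89 probes at an unadjusted p under 0.05). Every other split mixes the groups compared, so that a real difference enters its spread within groups. The 0 calls of those splits are therefore no measure of chance. For the lists, 2 splits gave as many as the real 17 at 6 h, the highest other giving 17, and 1 at 24 h, where the real split gave 15 and the highest other 12. These mixed splits keep part of the real difference between the media, so their list counts are no measure of chance either. Of 100 drawn splits of the 12 arrays within times, 2 gave at least the 6559 interaction calls. The higher one, with 7785, swapped the media at 24 h alone, so that its contrast adds the effects of both times. Mixed splits lose the effects of the medium at each time as well, so this count does not bear on whether chance gave the interaction.

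Markers of astrocytes, oligodendrocyte lineage, neurons and fibroblasts were lower in aSCM than in LZCM at 24 h, with a median of -1.41 over 36 genes. The 3 other scalings left this in place (-1.37 without background correction, -1.42 with scaled medians and -1.38 in the authors' values). The first was still quantile-normalized and the authors' values lay close to it, so scaled medians alone argue against quantile normalization as the cause. All of these give the arrays a common centre, so none can show a difference in total RNA. From 6 h to 24 h the medians of the astrocyte, fibroblast, neuronal and oligodendrocyte lists changed by 0.93, 0.85, 0.63 and 0.22 in LZCM (camera adjusted p = 9.25e-07, 0.00978, 0.00569 and 0.0369; adjusted p = 0.0155, 0.0857, 0.0715 and 0.31 with an estimated correlation) and by -0.48, -0.54, -0.42 and -0.55 in aSCM (0.0405, 0.0593, 0.0512 and 0.149; 0.148, 0.207, 0.207 and 0.445). With 3 oligodendrocyte-lineage members below the ceiling set to their bound, that list's median over time in aSCM was -0.02 in place of -0.55. Fewer non-microglial cells in aSCM than in LZCM at 24 h, by loss in aSCM or growth in LZCM, may account for the gap between the media. The lists had been seen to differ first, so the share that was lower could not test it. Of the 29 members at least 1 log2 above the ceiling in LZCM, 28 fell and none rose (96.6%). Of all 36, 32 fell and 2, Nefl and Nefm, rose. Chosen by the mean over all 12 arrays, 21 of 23 fell and 1, Nefl, rose; the brightest in LZCM were Olig1 (14.68 log2), Gap43 (13.66) and Sparcl1 (12.88). Regulation inside such cells and an effect of α-synuclein on them cannot be told apart from a difference in their number here, Aldoc is shared with the glycolysis list, and macrophages can also make Fn1.

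Cell-cycle genes fell at both times, and fewer dividing non-microglial cells could lower them. At 6 h this stays open, since the non-microglial markers at least 1 log2 above the ceiling went both ways (18 of 23 fell and 3 rose), so that their mean of -0.47 does not measure cell number; cell-cycle genes had a mean of -0.87 over 27 (difference -0.40, two-sided permutation p = 0.0204). At 24 h, where 28 of 29 such markers fell, cell-cycle genes fell by less (-1.26 over 28 and -1.83 over 29, difference 0.56, two-sided permutation p = 0.00947), as fewer such cells would allow. From 6 h to 24 h in LZCM, however, the astrocyte, fibroblast and neuronal medians rose by 0.93, 0.85 and 0.63. Cell-cycle genes did not rise with them (median -0.02, 5 rose and 11 fell, camera adjusted p = 0.574). Both permutations treated genes as independent, so their p-values can be too small. Fewer cells of one dividing type alone and a slower cycle in microglia, a biological account that the medium groups allow, were not tested.

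Interferon-stimulated genes were lower at 24 h than at 6 h in LZCM while astrocyte markers rose, so dilution of microglial RNA by other cells may contribute. The interferon genes fell by more than the microglia and macrophage markers, with means of -0.96 over 28 and -0.45 over 11 (difference -0.51, two-sided permutation p = 0.029). With genes chosen by the mean over all 12 arrays, the difference was -0.53 (two-sided permutation p = 0.0279). The permutation treated genes as independent, while the estimated correlation between interferon genes was 0.29. Its p-values can therefore be too small, and whether dilution was the whole account was not decided. A transient stimulus common to both media stays open, since no untreated microglia were analysed here.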

How the results depend on the processing

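The alternatives chosen after seeing the data were the offset of 16, the receptor probes as negative controls, the filter at the background ceiling and the homeostatic list without Siglec5; neqc with an offset of 50 and a detection filter were not run for want of detection p-values, nor the chip as a block, since no chip is named. 1 list turned its direction past the threshold: over time in LZCM the unfolded protein list pointed down by camera (adjusted p = 0.889) and up by fry (0.0477); the cause was not tested. Of 3448 values of named genes under the settings other than leaving out an array, 12 lost and 3 gained a call, and of 868 list values 27 lost and 39 gained one. Lists in the interaction and over time were run under the other scalings, an estimated correlation and fry alone: under the scalings no call was lost, and with scaled medians NF-kB genes (0.0344, interaction), lysosome genes (0.0456, LZCM), neuronal markers (0.046, aSCM) and NRF2 targets (0.0307, aSCM) passed, all downwards, as did neuronal markers in the authors' values (0.0447). With array medians scaled, 3 lists were lower at 6 h instead of 6; the cause was not tested. Requiring a 1.5-fold change, stricter by construction, left 1394 up and 1659 down at 6 h, 1312 and 1582 at 24 h, 1867 and 1883 in the interaction, 703 and 617 over time in LZCM, 1768 and 1701 over time in aSCM, and 488 and 549 shared. With an estimated correlation, 6 lists were higher and 1 lower at 6 h, and 4 and 2 at 24 h. Adjusted p also rose where the estimate was under the preset 0.01, as for alternative-activation markers at 24 h (estimate 0, camera adjusted p from 0.00501 to 0.0506). The size of the estimate therefore does not account for every lost call. The values given with an estimated correlation do not measure correlation between genes alone. Fry, which does not compare a list with other genes, gave 17 and 11 at 6 h, 18 and 13 at 24 h, 10 and 18 in the interaction, 8 and 15 in LZCM and 7 and 23 in aSCM. Leaving out 1 array at a time gave 2910 to 3149 up and 3619 to 3891 down at 6 h, 3430 to 3853 and 3166 to 3499 at 24 h, 3266 to 3427 and 2991 to 3130 in the interaction, 1998 to 2461 and 2069 to 2554 in LZCM, 3831 to 4017 and 3283 to 3457 in aSCM, and 1513 to 1655 and 1760 to 1907 shared; lists were 11 to 11 up and 5 to 6 down at 6 h, and 9 to 10 and 6 to 7 at 24 h. Without 1 array, 11 of 3828 gene values lost and 2 gained a call, all in Hspe1, Myd88, Bag3, Dnaja1 and Cldn5, and 2 of 744 list values lost and 6 gained one. The replicate number as a block gave 3181 and 3909 at 6 h, 3818 and 3466 at 24 h, 3508 and 3212 in the interaction, 2374 and 2462 in LZCM, 4077 and 3523 in aSCM and 1684 and 1915 shared, and the same numbers of lists, 11 and 6 at 6 h and 9 and 6 at 24 h. Same-numbered arrays correlated in their deviations at -0.05, 0.18 and 0.09 at 6 h and 0.17, 0.02 and 0.25 at 24 h. The highest correlations with another number were 0.04, -0.08 and 0.09 at 6 h and 0.02, 0.06 and -0.04 at 24 h. Not every array correlated best with its own number, and a weak pairing by number was neither shown nor excluded. Signal over background limits the dim genes: of 11262 probes, 8887 exceeded the ceiling on all 12 arrays.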

Other observations

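The account of 24 h against 6 h was chosen after the results were seen for the lists named here. In LZCM, NF-kB genes fell over time in 14 of 15 members (camera adjusted p = 3.92e-06), prostaglandin and nitric oxide enzymes in 14 of 17, or 15 adjusted over the list alone (1.72e-06), and inflammatory cytokines in 6 of 14 (0.0128; adjusted p = 0.213 with an estimated correlation), while heat shock proteins rose in 6 of 9 (0.0267; adjusted p = 0.118 with an estimated correlation). Microglia and macrophage markers also fell, in 10 of 11 with a median of -0.37, against a median of -0.50 for NF-kB genes. Dilution of microglial RNA was not tested for these falling lists. Oligodendrocyte-lineage markers rose in 5 of 11, or 6 adjusted over the list alone, and fell in 1 (0.0369, or 0.31 with an estimated correlation). Fibroblast and pericyte markers rose in 5 of 6 (0.00978, or 0.0857 with an estimated correlation). In aSCM, oxidative phosphorylation genes rose over time in 18 of 26 (0.0297, or 0.213 with an estimated correlation) and glycolysis genes in 14 of 21 (0.0469, or 0.244 with an estimated correlation). Cell-cycle genes fell in 23 of 29 with a median of -0.46 (1.9e-04, or 0.0644 with an estimated correlation). In the same comparison the astrocyte, fibroblast and neuronal medians were -0.48, -0.54 and -0.42. The fitted oligodendrocyte-lineage median was -0.55, with 6 of 11 lower and 2 higher. With 3 members below the ceiling set to their bound, a lower limit of the change, it was -0.02.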
